A study of Escherichia coli with 9 samples.

How the data were processed

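The data were RNA-seq read counts of 9 E. coli libraries, 3 for each of the strains Star, S-AB and SfB-ABCFPfA. Strain and replicate number were taken from the sample titles and strain labels, and each column was matched to its sample through the abbreviation given in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made by standard Illumina methods. Per the submitters' processing notes, bcl2fastq 2.17.1.14 and Bowtie2 2.2.6 were used. The counting tool, the annotation tool, the strand setting and the growth conditions are not given in the sources used here.

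The deposited table gave, for each of 4237 genes, a raw count and an FPKM value per library, the position on a sequence named BL21-DE3-Star, a coding length and COG, KEGG and GO annotation. The counts were whole numbers, as the authors' column headers say. The deposited FPKM equalled, within 0.01, the FPKM computed from the count, the coding length and the column total. All coding lengths were multiples of 3, so the gene models hold no untranslated regions; no rRNA or tRNA genes and no total or unassigned lines were in the table used here. No other columns of per-sample values were present.

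The table carried no gene symbols. A symbol of E. coli K-12 MG1655 (assembly ASM584v2) was given where the COG name of a gene matched a K-12 symbol or synonym one to one and the coding lengths were equal (1187 genes), or, for the sole gene of its COG, within 3% (28 genes). Of these 1215 genes, 4 lay out of place by over 100 kb among their named neighbours and lost their symbol, leaving 1211. Adjacent named genes lay within 20 kb of each other in K-12 in 596 of 597 cases (99.8%). This naming procedure was set after the table was seen. Genes without a symbol keep their number in the table, such as 1_3333. Coordinates are those of the deposited table, and none were taken from K-12.

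Changes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 3682 genes; the 555 left out, 62 of them without a count in any library, held 0.0296% of all counts. Library sizes were scaled by TMM. All 9 libraries entered a single quasi-likelihood fit (glmQLFit with robust estimation) with strain as the only term, so that the strains shared an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM are counts relative to the scaled library size, printed with the SD over 3 libraries; principal components used log2 CPM with a prior count of 2. The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

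Gene lists were tested with camera in limma 3.58.1, which compares a list with all other genes, using a preset correlation between genes of 0.01 and, beside it, a correlation estimated from the libraries. Of 46 lists fixed beforehand with 868 entries, 524 entries had a gene with that symbol here, and the 35 lists with at least 5 tested genes were tested. With the estimated correlation no list passed in any comparison. A list's deviation in a library is the median over its genes of log2 CPM minus the strain mean.

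Genes named for each comparison were the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, with a mean of at least 50 counts per library and no overlap of CPM between the strains; up to 2 higher and 2 lower without a symbol; up to 4 called members of each list past the camera threshold; called genes for RNases, and lon; near-absent genes; and the 4 most abundant called genes. The genes rne, lacI, lacZ and rpoH were named in the rule too and had no gene with that symbol here, so they were not analysed here. Neighbours of the near-absent genes, further list members such as ndh, rpsU, cheA and cheR, and the genes in the closing observations were chosen after their values were seen.

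For overlap between the comparisons that share the Star libraries, 20 sets of counts for all 9 libraries were simulated with no change between strains, from the fitted dispersions. The dispersion of a gene was the same for all strains in these sets. Ratios with 1 to 3 counts in a strain have exact binomial intervals at 95% on pooled counts, and a strain with 0 counts was compared at a floor of 3 counts in each library. With 3339239 to 6346215 counts per library, 3 counts corresponded to 0.412 to 0.898 CPM.

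The tests were tried on simulated counts for the S-AB and Star comparison, with 3682 genes and 200 changed genes in each of 5 runs. edgeR recovered 28% of the genes changed 2-fold and 91% of those changed 4-fold, and 5.20% of its calls were false; DESeq2 1.42.0 recovered 43.6% and 93.6%, with 9.90% false. The planted list was found in 5 of 5 runs and the unchanged list in 0. Genes were drawn independently of each other, and each gene had the same dispersion in all strains. The runs therefore do not test lists whose genes move together, nor strains of unequal spread. The estimated correlations here were 0.106 for flagella and 0.655 for ribosomal proteins in S-AB against Star.

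The alternatives were DESeq2 size factors or upper quartile scaling in edgeR; no filter, or at least 10 CPM in 3 libraries; a fit of only the 2 strains compared; the replicate number as a block; the DESeq2 Wald test; limma on log2 of the deposited FPKM plus 1 or plus 0.1; and leaving out each library in turn. Chosen after seeing the data were leaving out S-AB replicate 2 and SfB-ABCFPfA replicate 3 together, 1 surrogate variable from svaseq (sva 3.50.0), limma-voom with sample quality weights, and thinning all libraries to the smallest total. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 in Python 3.11.15.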

Results

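RNA from 3 strains of Escherichia coli was sequenced, with 3 libraries per strain. Per the labels, the first strain was BL21(DE3) Star, called Star here, a laboratory strain of the B lineage that carries a gene for T7 RNA polymerase and is used to produce proteins. The other 2 strains were S-AB and SfB-ABCFPfA. The labels do not say what their letters stand for, nor what the tag mfLon, which all 9 titles carry, refers to. Total RNA was extracted with Trizol. Growth, harvest and sequencing batch are not given in the sources used here. The authors' table held 4237 protein-coding genes on a sequence of the strain, with a read count per library. Total counts were 3520652, 3394021 and 3339239 in the Star libraries, 5449623, 4840442 and 5254114 in the S-AB libraries and 6279154, 5680321 and 6346215 in the SfB-ABCFPfA libraries. Of these genes, 3682 had enough counts to be tested.

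The Star libraries lay close together and the libraries of the other strains were spread out. The biological coefficient of variation was 11.8% in Star, 29.5% in S-AB and 38.1% in SfB-ABCFPfA. Pearson correlations of log2 CPM, the read counts scaled to library size, between libraries of a strain were 0.984 to 0.989 in Star, 0.956 to 0.989 in S-AB and 0.931 to 0.973 in SfB-ABCFPfA, taken across genes, which are not independent replicates. The first principal component (42.6% of the variance) placed the Star libraries at -28.7 to -31.5 and the other 6 libraries at 6.49 to 18.7. On the second component (27.2%), S-AB replicate 2 lay at -21.7 against 14.4 and 15.4 for replicates 1 and 3. SfB-ABCFPfA replicate 3 lay at 27.5 against -28.9 and -13.1 for replicates 1 and 2. Ribosomal protein genes moved along with this spread in S-AB and in SfB-ABCFPfA replicate 3, but SfB-ABCFPfA replicates 1 and 2 did not follow its order. Their median deviation from the strain mean was -0.92 in S-AB replicate 2 against 0.50 and 0.36 in replicates 1 and 3, and 0.86 in SfB-ABCFPfA replicate 3 against -0.02 and -0.81 in replicates 1 and 2 (log2, 52 genes). No pair of libraries agreed within sampling noise; the smallest chi-square per degree of freedom was 2.18, between Star replicates 2 and 3. Nothing in the labels says that replicates came from separate cultures, so that the p-values measure only the spread between these samples, which may be technical.

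**Figure D1:**
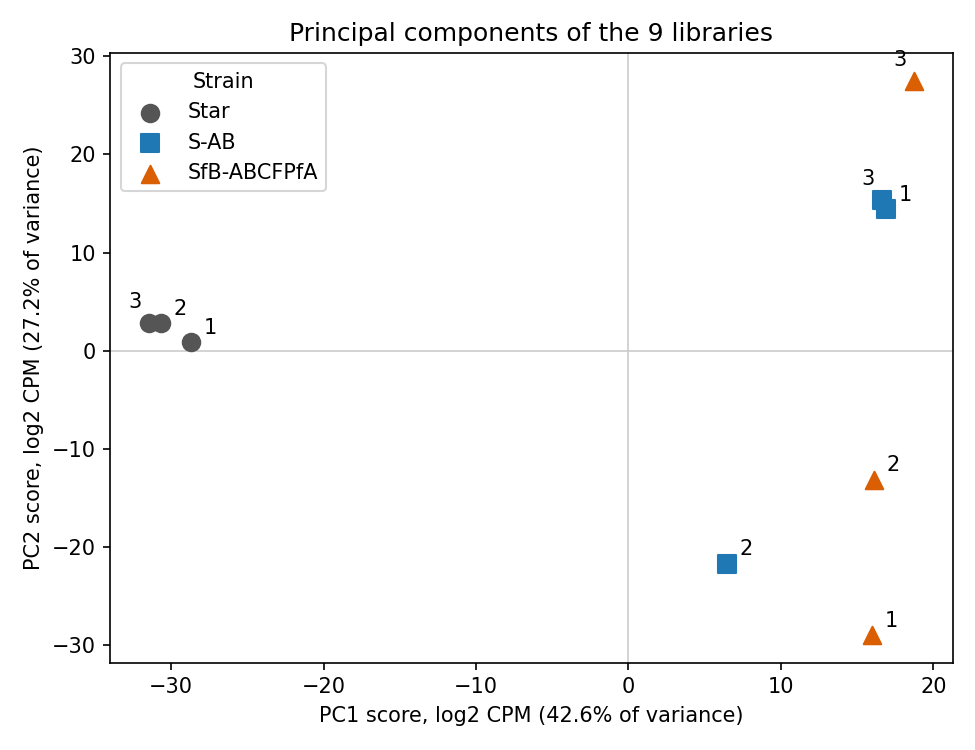
Scores of the 9 libraries on the first and second principal components of log2 CPM, with one symbol per strain and the replicate number beside each library. The Star libraries sit between -31.5 and -28.7 on the first component, S-AB replicate 2 sits at -21.7 on the second component and SfB-ABCFPfA replicate 3 at 27.5.

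The first comparison asked how the transcriptome of S-AB differed from that of Star. Of the gene lists tested, flagella and chemotaxis had the lowest median. The P-ring gene flgI (gene at 2617771 to 2618868 of the strain sequence) fell from 271 ± 9.96 CPM in Star to 20.5 ± 4.76 CPM in S-AB (SD, n = 3 each). The genes flhA and flhB of the flagellar export apparatus fell from 113 ± 20.6 to 14.8 ± 2.45 CPM and from 80.0 ± 8.09 to 9.38 ± 2.18 CPM. Genes of the respiratory chain were also lower, among them cydA of the cytochrome bd oxidase, which fell from 5558 ± 726 to 1940 ± 214 CPM. Of 6 genes for the use of glycerol 2 rose, among them glpA, for a subunit of anaerobic glycerol-3-phosphate dehydrogenase, from 182 ± 5.61 CPM in Star to 2088 ± 935 CPM in S-AB. The edgeR quasi-likelihood test called 269 genes higher and 293 lower in S-AB at a Benjamini-Hochberg adjusted p under 0.05, together 15.3% of the 3682 tested. Of these, 179 of the higher and 205 of the lower genes changed at least 2-fold. CPM values of the 2 strains did not overlap for 1590 genes (43.2%), against 10% from chance.

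Of the 22 tested genes of flagella and chemotaxis, 13 fell, none rose and 9 were not called, and adjusted over the list alone 13 fell as well. The list's median log2 fold change was -1.91 (adjusted p = 7.86e-18 by camera; adjusted p = 0.0506 with an estimated correlation). The 13 that fell were flhA, flhB, flgA to flgI, flgL and flgM, which encode the export apparatus, the basal body, the hook with its junction, factors for their assembly and an anti-sigma factor. The log2 fold changes of flgI, flgB, flgH and flgC were -3.72, -3.39, -3.20 and -2.74 (adjusted p = 0.000116, 0.00128, 0.000116 and 0.00404). The chemotaxis members were not called; cheR, for the receptor methyltransferase, had a log2 fold change of 0.99 (adjusted p = 0.213) and cheA, for the sensor kinase, one of -0.59 (adjusted p = 0.121). Gene 1_2461, of the FlgK family of hook-associated proteins and without a symbol here, fell by 2.69 on the log2 scale. The list's median deviations were -0.01, -0.17 and 0.20 in S-AB replicates 1, 2 and 3 (log2).

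Of the 28 tested genes of aerobic respiration and ATP synthase, 15 fell, none rose and 13 were not called, while adjusted over the list alone 17 fell. Their median log2 fold change was -1.01 (adjusted p = 1.76e-10 by camera; adjusted p = 0.127 with an estimated correlation). The genes cyoD and cyoE, for a subunit and the haem synthase of cytochrome bo oxidase, had log2 fold changes of -1.74 and -1.78 (adjusted p = 0.00160 and 0.00224). nuoM, a membrane subunit gene of NADH dehydrogenase I, fell from 949 ± 32.0 to 248 ± 56.9 CPM, and atpE, for the c subunit of ATP synthase, from 92.7 ± 7.87 to 28.4 ± 7.43 CPM. The genes atpH, atpA, atpG, atpD and atpC, which encode soluble parts of ATP synthase, were not called, with log2 fold changes of -0.28, -0.20, -0.22, -0.29 and -0.69.

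Among the 9 tested genes of branched-chain amino acid biosynthesis, 4 fell, none rose and 5 were not called, and 4 fell adjusted over the list alone (median log2 fold change -0.72, adjusted p = 0.00740 by camera; adjusted p = 0.664 with an estimated correlation). ilvC, the ketol-acid reductoisomerase gene, fell from 6225 ± 1805 to 1242 ± 657 CPM (adjusted p = 0.0215), leuD from 226 ± 4.40 to 36.6 ± 17.7 CPM, and leuB and leuC had log2 fold changes of -1.12 and -1.06. The leu genes encode enzymes of leucine synthesis. The list deviated by -0.07, 0.37 and -0.32 in S-AB replicates 1, 2 and 3.

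Among the 6 tested glycerol genes, glpA and glpF rose, none fell and 4 were not called, and 3 rose adjusted over the list alone (median log2 fold change 2.01, adjusted p = 0.0322 by camera; adjusted p = 0.730 with an estimated correlation). glpF, the glycerol channel gene, rose from 264 ± 4.70 to 1062 ± 472 CPM. The glycerol list deviated by -0.16, 0.96 and -0.89 in S-AB replicates 1, 2 and 3, and its adjusted camera p was 0.15 without S-AB replicate 2 and 0.0511 without Star replicate 2. Of the 10 tested genes of aromatic amino acid biosynthesis, 2 rose, none fell and 8 were not called, with 2 higher adjusted over the list alone (median log2 fold change 0.59, adjusted p = 0.0322 by camera; adjusted p = 0.664 with an estimated correlation). aroE, for shikimate dehydrogenase, rose from 108 ± 14.4 to 240 ± 17.5 CPM and aroC, for chorismate synthase, from 70.2 ± 10.6 to 136 ± 28.1 CPM. This list deviated by 0.16, -0.36 and 0.16 in S-AB replicates 1, 2 and 3. Without S-AB replicate 1 or 3 its adjusted camera p was 0.0525 or 0.102.

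Single genes outside these lists changed by as much. speE, for spermidine synthase (gene at 3597302 to 3598168), rose from 46.6 ± 4.72 to 385 ± 163 CPM, with a log2 fold change of 3.05 ± 0.52 (SE, adjusted p = 0.00442). The methionine genes metF and metA rose by 2.72 and 2.01 on the log2 scale (adjusted p = 0.00160 and 0.00172). waaG, a lipopolysaccharide core glycosyltransferase gene, rose from 17.4 ± 2.88 to 91.3 ± 44.4 CPM, fabH, for an enzyme that starts fatty acid synthesis, from 110 ± 6.51 to 383 ± 128 CPM, and mobB, a molybdenum cofactor gene, from 9.76 ± 1.65 to 36.7 ± 12.4 CPM. Gene 1_3019, of 606 bases and of the OmpC porin family, rose from 32.8 ± 3.68 to 557 ± 361 CPM. How reads shared with other porin genes were counted is not given in the sources used here. sulA, the cell division inhibitor of the SOS response, fell from 103 ± 3.86 to 13.2 ± 2.66 CPM, mglC, for a galactose permease subunit, from 74.0 ± 15.2 to 11.3 ± 4.87 CPM, and gene 1_1690, which has no annotation in the table, from 35.8 ± 6.89 to 4.16 ± 0.598 CPM. Among abundant transcripts, ftsH, for a membrane protease, fell by 0.86 and pepD, a dipeptidase gene, rose by 0.81 on the log2 scale. The protease gene lon had 46.9 ± 5.12 CPM in Star and 52.8 ± 9.74 CPM in S-AB (adjusted p = 0.669). Of the 13 tested genes for RNases and RNA turnover, rbn alone was called, at 10.5 ± 0.544 CPM in Star and 21.9 ± 6.15 CPM in S-AB (adjusted p = 0.0391), and none was called adjusted over the list alone (adjusted p = 0.412 by camera).

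No other list passed the camera test in S-AB. No gene of the 52 ribosomal protein genes was called (median log2 fold change 0.53, adjusted p = 0.0569 by camera), and the deviations of this list are given above with the libraries. In lysine and threonine biosynthesis 1 of 9 genes rose, or 6 adjusted over the list alone (adjusted p = 0.0667 by camera). A single gene rose in fatty acid biosynthesis and in pyrimidine biosynthesis (adjusted p = 0.148 by camera each), in nitrogen assimilation (0.966) and among aminoacyl-tRNA synthetases (0.509), and 2 rose in arginine biosynthesis (0.349) and in methionine and sulfur assimilation (0.431). A single gene fell in osmotic stress (adjusted p = 0.133 by camera), sugar uptake and catabolism (0.267), general stress (0.509), envelope stress (0.509), glycolysis (0.598), DNA replication (0.797), RNA polymerase and transcription factors (0.878) and metal efflux (0.878). In amino acid catabolism (adjusted p = 0.272 by camera), the TCA cycle (0.279) and heat shock (0.317) 2 genes fell, and in iron acquisition 3 fell (0.313). Both directions occurred in phosphate starvation (1 higher and 2 lower, adjusted p = 0.199 by camera), SOS DNA damage (1 and 2, 0.317), cell division and murein (1 and 2, 0.412) and anaerobic respiration (1 and 1, 0.424). No gene was called in purine biosynthesis, acetate metabolism, oxidative stress, the pentose phosphate pathway or histidine biosynthesis (adjusted p = 0.279 by camera, 0.424, 0.528, 0.587 and 0.709). Adjusted over the list alone, the numbers differed in phosphate starvation (1 higher and 4 lower), methionine and sulfur assimilation (4 higher), arginine biosynthesis and SOS DNA damage (2 and 2 each), cell division (2 and 4), anaerobic respiration (1 and 2), RNA polymerase and metal efflux (1 and 1 each), and aminoacyl-tRNA synthetases and glycolysis (0). The median and the mean had opposite signs in methionine and sulfur assimilation (-0.08 and 0.19) and in nitrogen assimilation (-0.0028 and 0.098), where camera placed the lists higher. RNA polymerase and transcription factors had a median of 0.18 and a mean of 0.03, and camera, which compares with all other genes, placed that list lower.

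The counts for S-AB depended on the libraries used: without Star replicate 1, 2 or 3 they were 97, 55 and 67 higher and 138, 109 and 115 lower. Without S-AB replicate 1 or 3 they were 96 and 134 higher and 106 and 146 lower. Without S-AB replicate 2 they were 300 higher and 354 lower. They were larger when only the libraries of the 2 strains were fitted (465 higher and 449 lower), with sample quality weights (951 and 914), with 1 surrogate variable (660 and 643) and with S-AB replicate 2 and SfB-ABCFPfA replicate 3 both left out (709 and 685).

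**Figure D2:**
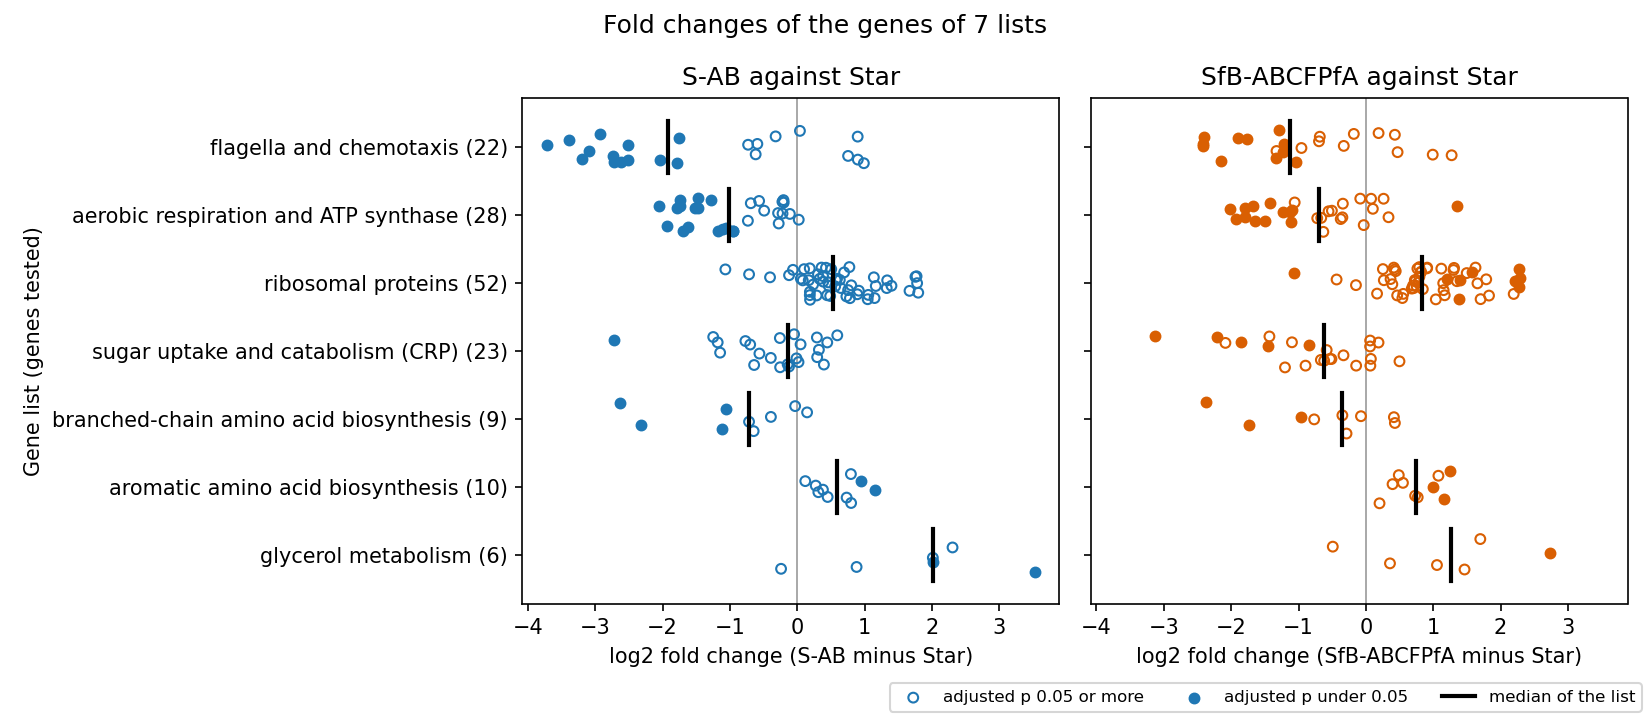
Log2 fold changes against Star of the tested genes of 7 gene lists, for S-AB (blue, left panel) and SfB-ABCFPfA (orange, right panel); filled points have an adjusted p under 0.05, open points do not, black bars are list medians, and the number of genes stands in brackets. The flagella and chemotaxis list has medians of -1.91 and -1.12, and that of the ribosomal proteins lies at 0.53 and 0.83.

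The second comparison asked how SfB-ABCFPfA differed from Star. Flagellar genes were lower in this strain too, with flgI at 50.6 ± 18.6 CPM against 271 ± 9.96 CPM in Star and flhA at 21.3 ± 6.76 against 113 ± 20.6 CPM (SD, n = 3 each). Of 52 ribosomal protein genes 8 rose and 1 fell, with rpsJ, for protein S10, rising from 694 ± 60.7 to 3208 ± 2029.8 CPM. The maltose uptake genes malG, malE and malK were lower: malG, for a permease subunit, fell from 794 ± 62.0 to 90.1 ± 112 CPM and malE, for the periplasmic maltose-binding protein, from 2925 ± 378 to 633 ± 590 CPM. In replicates 1, 2 and 3 malG had 22.6, 28.0 and 220 CPM and malE 196, 398 and 1305 CPM. The largest fall of a gene with a symbol was that of hmp, the flavohaemoglobin that removes nitric oxide, from 1142 ± 579 to 68.6 ± 29.2 CPM (log2 fold change -4.06 ± 0.61, SE, adjusted p = 0.00252). Against S-AB the difference of -3.38 was not called (adjusted p = 0.127). The edgeR quasi-likelihood test called 368 genes higher and 334 lower (19.1% of those tested), and 262 and 232 of them changed at least 2-fold. CPM values did not overlap for 1503 genes (40.8%), against 10% from chance.

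Of the 22 tested genes of flagella and chemotaxis, 11 fell, none rose and 11 were not called; adjusted over the list alone, 13 fell and 1 rose. The median log2 fold change was -1.12 (adjusted p = 2.73e-07 by camera; adjusted p = 0.359 with an estimated correlation). flgI, flhA, flhB and flgH had log2 fold changes of -2.42, -2.42, -2.40 and -1.90 (adjusted p = 0.000593, 0.000593, 0.000765 and 0.00115). The list's median deviations were 0.30, -0.27 and -0.01 in SfB-ABCFPfA replicates 1, 2 and 3.

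In aerobic respiration and ATP synthase, 12 of 28 genes fell, 1 rose and 15 were not called, and 16 fell and 1 rose adjusted over the list alone (median log2 fold change -0.69, adjusted p = 3.09e-06 by camera; adjusted p = 0.359 with an estimated correlation). cyoD, cyoE, cydA and atpE had log2 fold changes of -1.80, -1.93, -1.80 and -1.49 (adjusted p = 0.0014, 0.00157, 0.00298 and 0.00339). The gene that rose was ndh, for NADH dehydrogenase II, a single-subunit enzyme that pumps no protons, from 865 ± 140 to 2211 ± 652 CPM (adjusted p = 0.00886; 1.56 against S-AB on the log2 scale, adjusted p = 0.127).

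Of the 52 tested ribosomal protein genes, 8 rose, 1 fell and 43 were not called, with the same numbers adjusted over the list alone (median log2 fold change 0.83, adjusted p = 0.000550 by camera; adjusted p = 0.818 with an estimated correlation). rplC, rplD and rplW, which lie next to rpsJ at 458086 to 459974, had log2 fold changes of 2.28, 2.29 and 2.27, with standard errors of 0.62, 0.64 and 0.58. rpsA, for protein S1, rose from 2610 ± 90.6 to 7755 ± 3916 CPM, rplT from 2415 ± 231 to 6380 ± 3142 CPM, rpmI from 286 ± 6.86 to 743 ± 380 CPM and rpmB from 723 ± 84.1 to 1670 ± 255 CPM. In contrast, rpsU, for protein S21, fell by 1.07 on the log2 scale. The ribosomal deviations of -0.02, -0.81 and 0.86 in SfB-ABCFPfA replicates 1, 2 and 3 stand beside this result. Without replicate 3 the adjusted camera p of the list was 0.205.

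In sugar uptake and catabolism, 5 of 23 genes fell, none rose and 18 were not called, and 7 fell adjusted over the list alone (median log2 fold change -0.62, adjusted p = 0.00478 by camera; adjusted p = 0.540 with an estimated correlation). Besides malG and malE these were malK, for the ATPase of maltose uptake, mglC, which fell by 1.45 on the log2 scale, and mtlA, the mannitol transporter gene, which fell from 205 ± 11.8 to 114 ± 8.14 CPM. This list deviated by 0.04, 0.03 and -0.11 in SfB-ABCFPfA replicates 1, 2 and 3. Gene 1_3911, of the UgpA family of sugar permeases, lies beside malG at 4143075 to 4144619 and fell from 679 ± 45.2 to 68.4 ± 53.1 CPM. In aromatic amino acid biosynthesis 3 of 10 genes rose, none fell and 7 were not called, with 5 higher adjusted over the list alone (median log2 fold change 0.75, adjusted p = 0.00603 by camera; adjusted p = 0.540 with an estimated correlation). aroG, for the first enzyme of the pathway, rose from 565 ± 4.20 to 1259 ± 477 CPM, aroE from 108 ± 14.4 to 258 ± 17.6 CPM and aroC from 70.2 ± 10.6 to 140 ± 27.0 CPM. The list deviated by -0.28, 0.01 and 0.19 in SfB-ABCFPfA replicates 1, 2 and 3, and without replicate 3 its adjusted camera p was 0.0808.

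speE rose from 46.6 ± 4.72 to 1122 ± 757 CPM (log2 fold change 4.59 ± 0.55, adjusted p = 0.000771), glpA from 182 ± 5.61 to 1203 ± 741 CPM, waaG from 17.4 ± 2.88 to 96.1 ± 69.3 CPM, and mcrB, a gene of a restriction system that acts on methylated DNA, from 42.0 ± 6.03 to 208 ± 81.3 CPM. Gene 1_3019 of the OmpC family rose from 32.8 ± 3.68 to 1938 ± 2003 CPM, with a log2 fold change of 5.89 ± 0.91. Its replicates had 4158, 1390 and 267 CPM. sulA, leuD and cpxP, a periplasmic gene of the Cpx envelope stress response, had log2 fold changes of -2.80, -2.37 and -2.35. Gene 1_3725, whose family is described in the table as regulators of morphogenesis and nitric oxide signalling, fell from 117 ± 44.2 to 9.96 ± 4.16 CPM. Among abundant transcripts, ompA, for a major outer membrane protein, rose by 1.55 and nlpI, for a lipoprotein, fell by 1.09 on the log2 scale. lon had 57.6 ± 14.7 CPM (adjusted p = 0.411 against Star).

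The other lists did not pass the camera test. In fatty acid biosynthesis 4 of 12 genes rose, in pyrimidine biosynthesis 2 of 9 and in arginine biosynthesis 2 of 10 (adjusted p = 0.0644 by camera, 0.126 and 0.325). In branched-chain amino acid biosynthesis leuB, leuC and leuD fell, 3 of 9 (adjusted p = 0.0644 by camera), while ilvC had 6225 ± 1805 CPM in Star and 5919 ± 4534 CPM in SfB-ABCFPfA (adjusted p = 0.940; against S-AB log2 fold change 2.25, adjusted p = 0.317). In amino acid catabolism, cell division and murein, and iron acquisition 4 genes fell each (adjusted p = 0.0644 by camera, 0.137 and 0.157). In osmotic stress, the TCA cycle and SOS DNA damage 2 fell each (0.130, 0.251 and 0.535). Of the 6 glycerol genes of the list glpA alone was called (adjusted p = 0.251 by camera). The GO term glycerol catabolic process, tested after the data were seen, had 4 of 8 genes higher. Its adjusted p was 0.0310 by camera and 0.818 with an estimated correlation. Both directions occurred in phosphate starvation (1 higher and 2 lower, adjusted p = 0.157 by camera), methionine and sulfur assimilation (3 and 1, 0.372), nitrogen assimilation (1 and 1, 0.500), anaerobic respiration (1 and 1, 0.407), general stress (1 and 1, 0.605), glycolysis (2 and 1, 0.832) and envelope stress (2 and 1, 0.995). Among aminoacyl-tRNA synthetases 2 genes rose (adjusted p = 0.407 by camera), and 1 rose in lysine and threonine biosynthesis (0.407) and in metal efflux (0.747), while 1 fell in acetate metabolism (0.350) and in DNA replication (0.804). No gene was called among RNases, heat shock, histidine biosynthesis, purine biosynthesis, oxidative stress, the pentose phosphate pathway or RNA polymerase and transcription factors (adjusted p = 0.384 by camera, 0.535, 0.500, 0.553, 0.779, 0.435 and 0.989). Adjusted over the list alone, the numbers differed in fatty acid biosynthesis (5 higher), branched-chain biosynthesis (4 lower), cell division (5 lower), phosphate starvation (1 higher and 5 lower), nitrogen assimilation (2 and 3), metal efflux (1 and 1), aminoacyl-tRNA synthetases (1 higher) and lysine and threonine biosynthesis (0). The median and the mean had opposite signs in SOS DNA damage (0.13 and -0.16), where camera placed the list lower, and in glycolysis (-0.08 and 0.09), where it placed the list higher. Camera also placed lower DNA replication and envelope stress, whose medians and means were above 0.

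Without Star replicate 1, 2 or 3 the counts for SfB-ABCFPfA were 175, 122 and 123 higher and 209, 142 and 156 lower. They were 685 higher and 676 lower with sample quality weights, 756 and 708 with 1 surrogate variable, and 727 and 664 with S-AB replicate 2 and SfB-ABCFPfA replicate 3 both left out.

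**Figure D3:**
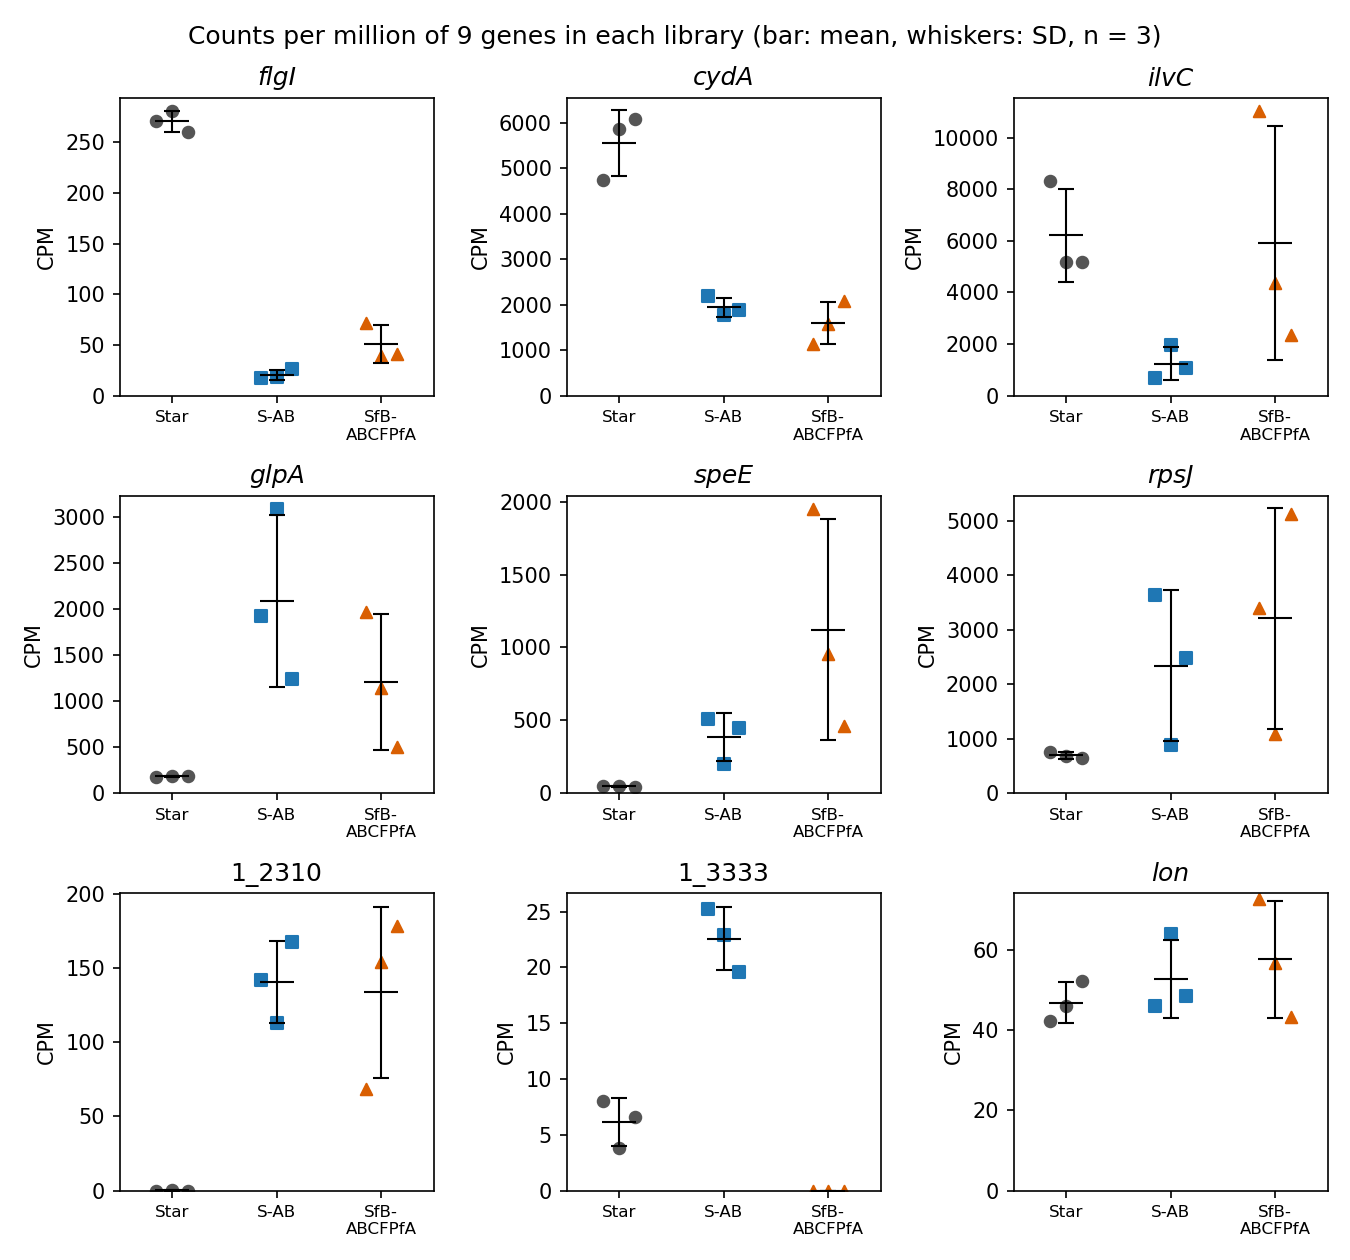
CPM of 9 genes in each library, with bars at the strain mean and whiskers of 1 SD (n = 3 per strain). flgI falls from a mean of 271 CPM in Star to 20.5 and 50.6 CPM, gene 1_2310 is near 0 in Star, gene 1_3333 is at 0 in all 3 SfB-ABCFPfA libraries, and lon stays between means of 46.9 and 57.6 CPM.

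Many genes were called in both strains against Star. Of the higher genes 211 were shared, against 26.9 for independent lists of these sizes, and of the lower genes 223, against 26.6; 1 gene, 1_3333, went in opposite directions. Both strains shared the falls of flgI, flgH, flhA, flhB, sulA, leuD, cyoD and cydA and the rises of speE, glpA, waaG and aroE. Across the tested genes the fold changes correlated with r = 0.833 and rho = 0.856, where 9 libraries simulated with no change between strains gave medians of 0.531 and 0.493 (20 simulations). The simulations gave no shared calls, but they called at most 1 gene per comparison and direction. They therefore cannot show how far the shared Star libraries raise the number of shared calls. The covariance was 0.588 against a simulated 0.0859, a difference of 0.502. In these simulations each gene had the same dispersion in all strains. The biological coefficient of variation was 11.8% in Star, 29.5% in S-AB and 38.1% in SfB-ABCFPfA. The simulated correlations and covariance are therefore not those that Star libraries of this smaller spread would give. The 3 Star libraries cannot be divided into groups of at least 2, so part of the excess in shared calls may come from the shared controls.

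The third comparison set SfB-ABCFPfA against S-AB. Gene 1_3333, of the release factor B family (COG1186), was the only gene called by edgeR: it had 147, 99 and 116 counts in the S-AB libraries and 0 in each SfB-ABCFPfA library. No gene was called higher. At an unadjusted p under 0.05, 127 genes were higher and 101 lower, where 184 of 3682 are expected from chance, and DESeq2 called 20 higher and 12 lower at its adjusted threshold. CPM values did not overlap for 301 genes (8.17%), against 10% from chance. No gene of any list was called in this comparison. Without SfB-ABCFPfA replicate 3 the edgeR counts were 16 higher and 9 lower, without SfB-ABCFPfA replicate 1 they were 2 higher and 1 lower, and with S-AB replicate 2 and SfB-ABCFPfA replicate 3 both left out they were 324 higher and 277 lower. They were 39 and 32 with 1 surrogate variable, 31 and 25 with sample quality weights, and 0 and 2 with the replicate number as a block.

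The flagella and chemotaxis list lay higher in SfB-ABCFPfA than in S-AB by a median log2 fold change of 0.48 (adjusted p = 1.03e-10 by camera; adjusted p = 0.196 with an estimated correlation). None of the 22 genes was called over all genes and 9 were higher adjusted over the list alone. flgI differed by a log2 fold change of 1.30 (adjusted p = 0.185) and flgH by 1.30 (adjusted p = 0.160). The heat shock list had a median of 0.82 (adjusted p = 0.000133 by camera; adjusted p = 0.762 with an estimated correlation), with none of 14 genes called either way. Its deviations were 1.09, -0.22 and -0.69 in SfB-ABCFPfA replicates 1, 2 and 3, and without replicate 1 its adjusted camera p was 0.433. The sugar list lay lower, with a median of -0.33 (adjusted p = 0.000967 by camera; adjusted p = 0.754 with an estimated correlation), with malE at -2.06 (adjusted p = 0.466) and malG at -1.99 (adjusted p = 0.640). It deviated by 0.33 in S-AB replicate 2, without which its adjusted camera p was 0.207. The ribosomal list had a median of 0.40 (adjusted p = 0.00418 by camera; adjusted p = 0.869 with an estimated correlation) and its direction turned without S-AB replicate 2 (0.732) or SfB-ABCFPfA replicate 3 (0.434).

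Of the remaining lists, glycerol metabolism had a median of -0.58, lysine and threonine biosynthesis one of -0.13 and aerobic respiration one of 0.19 (adjusted p = 0.0443 by camera each; adjusted p = 0.788, 0.762 and 0.762 with an estimated correlation). Histidine biosynthesis had a median of -0.42 (adjusted p = 0.0186 by camera; adjusted p = 0.762 with an estimated correlation). Adjusted over the list alone, 1 gene of aerobic respiration was higher and 1 of lysine and threonine biosynthesis lower. Without S-AB replicate 2 the adjusted camera p of these 4 lists was 0.913, 0.485, 0.0901 and 0.207, and without SfB-ABCFPfA replicate 3 it was 0.845, 0.686, 0.372 and 0.372. Aerobic respiration also missed the threshold without S-AB replicate 3 (0.221) or SfB-ABCFPfA replicate 1 (0.310), histidine biosynthesis without S-AB replicate 1 (0.117) or SfB-ABCFPfA replicate 2 (0.124), and lysine and threonine biosynthesis without SfB-ABCFPfA replicate 2 (0.0538). The other 27 lists did not pass, with adjusted camera p-values from 0.0574 for oxidative stress to 0.926 for osmotic stress. Among these, the median and the mean had opposite signs in general stress, the TCA cycle and osmotic stress, and phosphate starvation was placed lower with both above 0. Branched-chain amino acid biosynthesis, which did not pass either, had 1 gene higher adjusted over the list alone. lon had 52.8 ± 9.74 CPM in S-AB and 57.6 ± 14.7 CPM in SfB-ABCFPfA (adjusted p = 0.987).

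A gene was taken as near absent in a strain when its 3 libraries held at most 3 counts in all and another strain averaged at least 50 counts per library, and 3 genes met this. Gene 1_2310, a transposase gene of family COG3677 with a coding length of 276 bases (2461193 to 2461468), had 0, 1 and 0 counts in Star, 829, 487 and 995 in S-AB and 357, 887 and 1299 in SfB-ABCFPfA. The ratio to Star of pooled counts per library size was 1456 in S-AB (exact 95% interval 261 to 57532) and 1414 in SfB-ABCFPfA (253 to 55857). Its neighbour 1_2309, of the InsB family of IS1 transposases (2460771 to 2461148), had almost no counts in any strain. These were 0, 0 and 0 in Star, 1, 0 and 0 in S-AB and 0, 1 and 3 in SfB-ABCFPfA. Whether the reads of 1_2310 arose at this place was not tested. The gene on the other side, clsA, for a cardiolipin synthase, was not called, with log2 fold changes of -0.41 and -0.64 against Star (adjusted p = 0.242 and 0.0724). Gene 1_3626, of the XerD recombinase family (597 bases, 3843610 to 3844206), lies beside fimA, for the type 1 pilin. It had 1, 0 and 2 counts in Star, 44, 26 and 51 in S-AB and 123, 39 and 39 in SfB-ABCFPfA, with ratios of 25.4 (8.49 to 125) and 37.2 (12.6 to 182).

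Gene 1_3333 (423 bases, 3518472 to 3518894) had 27, 13 and 22 counts in Star, so that it rose in S-AB (log2 fold change 1.88 ± 0.32, adjusted p = 0.00804) and was missing from the SfB-ABCFPfA counts. Against the floor of 3 counts in each library, which averaged 0.504 CPM, SfB-ABCFPfA was at least 44.8-fold lower than S-AB and at least 12.2-fold lower than Star. Gene nlpE, for an outer membrane lipoprotein, ends just before it and had 171 ± 9.70, 167 ± 40.5 and 174 ± 10.5 CPM in Star, S-AB and SfB-ABCFPfA, and was not called in any comparison. Gene 1_3334 on its other side had 27.2 ± 6.24, 49.8 ± 10.5 and 123 ± 25.1 CPM, so that it rose against Star in S-AB (log2 fold change 0.87, adjusted p = 0.0458) and in SfB-ABCFPfA (adjusted p = 0.000856), with 1.30 between them (adjusted p = 0.172). It begins at 3518891, so the coding regions overlap, and whether the counting used the strand is not given in the sources used here. The intervals and the floor cover counting error only.

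**Figure D4:**
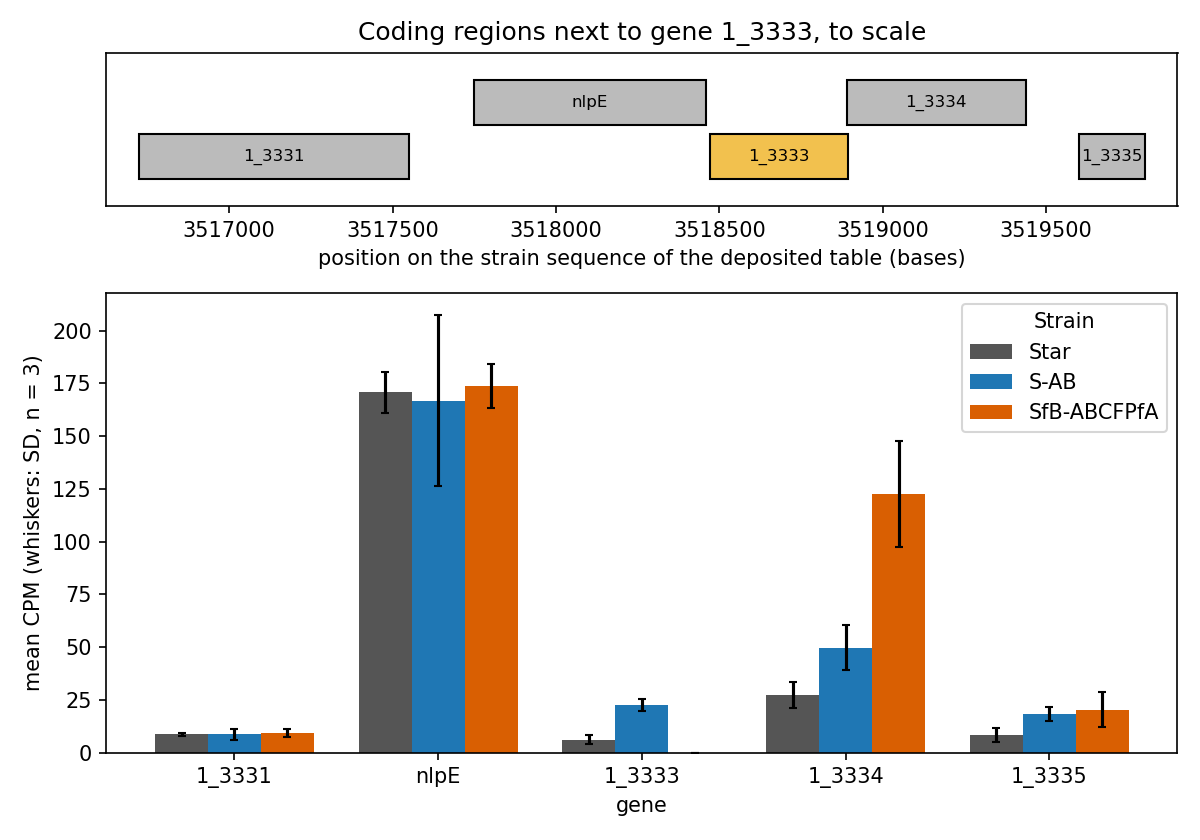
Coding regions around gene 1_3333 drawn to scale on the strain sequence (upper panel, position in bases; the height of a box has no meaning) and the mean CPM of each gene per strain (lower panel, whiskers of 1 SD, n = 3). Gene 1_3333 has means of 6.14 CPM in Star, 22.6 CPM in S-AB and 0 in SfB-ABCFPfA, while nlpE stays between 167 and 174 CPM and 1_3334 reaches 123 CPM in SfB-ABCFPfA.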

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

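The tests of a swap of libraries, of copies of gene 1_2310 and of other splits of the samples were chosen after the results they bear on were seen, as were thinning and the surrogate variable as settings; the outcomes that would decide the tests on depth, growth state and flagella were written down before their values were computed.

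Results were singled out here when a direct test between S-AB and SfB-ABCFPfA passed the threshold for a gene, or for a list that had also passed against Star in at least 1 of the strains. The heat shock, histidine and lysine and threonine lists passed between the strains (adjusted p = 0.000133, 0.0186 and 0.0443 by camera) but not against Star, and so were not singled out. Gene 1_3333 passed the direct test, with a fitted log2 fold change of -9.80 in SfB-ABCFPfA against S-AB, a value that depends on the prior count because SfB-ABCFPfA had 0 counts; against the floor it was at least 44.8-fold lower. The flagella and chemotaxis list differed with an adjusted p = 1.03e-10 by camera. The sugar uptake list had an adjusted p = 0.000967, and 0.207 without S-AB replicate 2. The ribosomal protein list had an adjusted p = 0.00418, but its direction turned without S-AB replicate 2 (0.732), without SfB-ABCFPfA replicate 3 (0.434) and with both left out (2.30e-07). The lists of aerobic respiration and of glycerol metabolism had an adjusted p = 0.0443 each. Aerobic respiration missed the threshold without S-AB replicate 2 (0.0901) or 3 (0.221) or SfB-ABCFPfA replicate 1 (0.310) or 3 (0.372). Glycerol metabolism missed it without S-AB replicate 2 (0.913) or SfB-ABCFPfA replicate 3 (0.845), and turned with both left out (0.155). With an estimated correlation none of these lists passed.

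S-AB replicate 2 and SfB-ABCFPfA replicate 3 lay apart from the other libraries of their strains. A swap of the pair was not decided, since the genes below go different ways. Of 599 genes called between the other 4 libraries of these strains, 425 had both libraries nearer the other strain and 31 had both nearer their own. These genes were called without the pair, and any axis that the pair shares with the other strain would give the same. By those 4 libraries 2 genes were near absent in a strain. Gene 1_3333 had 99 counts in S-AB replicate 2 and 0 in SfB-ABCFPfA replicate 3, as labelled. A swap would place those 99 counts in SfB-ABCFPfA, where replicates 1 and 2 had 0. Gene 1_766 had 3 and 0, as labelled in the first library and as in S-AB in the second. Its counts already varied within SfB-ABCFPfA, at 144 and 18 in replicates 1 and 2, so it is a weak marker of strain. An earlier test used gene 1_3333 alone, which had been picked with the labels, and was replaced. The deviations of the 2 libraries correlated across genes at -0.689 after thinning to equal totals and at -0.690 before, so the pattern did not need unequal totals. Thinning keeps the expected share of each gene in its library, so it could hardly have changed this correlation. It does not decide on other effects of depth. A different state of growth at harvest stays open, because the general stress list differed between the libraries by 0.28 on the log2 scale with an interval of -0.51 to 0.88 (9 genes, 10000 draws). The test used that list alone, and other lists differed by more. In S-AB replicate 2 and SfB-ABCFPfA replicate 3, ribosomal proteins deviated by -0.92 and 0.86 and glycerol metabolism by 0.96 and -1.16. Some lists deviated the same way in both libraries, such as aerobic respiration (0.14 and 0.12). Sequencing batch is not given in the sources used here, and no other biological explanation was tested.

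Flagellar genes were lower in both strains than in Star. After thinning to equal totals the list had adjusted p-values of 4.25e-22 in S-AB and 3.62e-09 in SfB-ABCFPfA by camera. The result therefore did not need the fewer counts in the Star libraries. Thinning keeps the expected share of each gene in its library, so it could hardly have moved the list and does not decide on other effects of depth. With 1 surrogate variable the medians were -1.99 and -1.14 (adjusted p = 2.74e-13 and 8.51e-06 by camera) and 13 genes fell in each. This cannot decide whether the axis along which the libraries of both strains spread is the cause. The variable was estimated with strain kept in the model, so it could hardly take up a difference between strains. A difference between the strains stays open as a hypothesis, and so does any difference in growth or handling that went with strain, which was not tested.

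Gene 1_2310 had reads in both strains and almost none in Star. Reads moved between the counted copies of its transposase family are argued against as the whole cause, since the family sum was at least 132 CPM in the libraries of both strains and at most 86.6 CPM in Star. This test replaced an earlier one on the other 27 family genes alone, whose sums of 63.0 to 111 CPM against 78.5 to 86.6 CPM in Star had not decided the question, and it was chosen after those values were seen. Copies outside the counted genes, and a copy of the element at a place that Star lacks, stay open.

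For the comparisons of S-AB and of SfB-ABCFPfA with Star, 1 of 10 splits of the 6 libraries gave as many genes in each case, the real one (562 and 702 genes, with 0 as the highest of the others), and 10 splits are too few for a share under 0.05. For SfB-ABCFPfA against S-AB, 2 of 10 splits gave at least the real 1 gene, and 10 splits are again too few. The highest other split called 960 genes and set S-AB replicates 1 and 3 with SfB-ABCFPfA replicate 3 against S-AB replicate 2 with SfB-ABCFPfA replicates 1 and 2. A swap of the pair would give this grouping, but gene 1_3333 lay as labelled in both libraries of the pair.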

How the results depend on the processing

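Leaving out S-AB replicate 2 and SfB-ABCFPfA replicate 3 together, the surrogate variable, the sample weights and thinning were chosen after seeing the data.

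Against Star, the counts stayed within 1.5 times of those reported with DESeq2 size factors, upper quartile scaling, no filter, the stricter filter, the replicate block, the DESeq2 test, limma on FPKM and thinning; over these, S-AB had 249 to 368 genes higher and 250 to 412 lower, and SfB-ABCFPfA 278 to 480 higher and 304 to 436 lower. With only the 2 strains fitted, S-AB had 465 genes higher and 449 lower. With both libraries left out the counts were 709 and 685 for S-AB, 727 and 664 for SfB-ABCFPfA, and 324 and 277 for SfB-ABCFPfA against S-AB. With 1 surrogate variable they were 660 and 643, 756 and 708, and 39 and 32, and with sample weights 951 and 914, 685 and 676, and 31 and 25. For SfB-ABCFPfA against S-AB, DESeq2 called 20 higher and 12 lower, and the replicate number as a block called 2 lower. The cause was not tested.

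Leaving out each library in turn gave 55 to 300 genes higher and 106 to 354 lower in S-AB, 122 to 488 higher and 142 to 443 lower in SfB-ABCFPfA, and 0 to 16 higher and 1 to 9 lower between them; a strain then had 2 libraries. The lists past the threshold numbered 4 to 10, 4 to 8 and 5 to 8, against 5, 5 and 8 as reported. With an estimated correlation 0 lists passed in each comparison. That test allows for genes of a list moving together, but this is not the whole reason. Osmotic stress in S-AB, with an estimated correlation of -0.051, went from an unadjusted p of 0.0305 to 0.0628 by camera. With both libraries left out 11 lists passed in S-AB, and without a filter 8 passed in SfB-ABCFPfA; the cause was not tested.

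Between SfB-ABCFPfA and S-AB the ribosomal list reversed without S-AB replicate 2 (adjusted p = 0.732), without SfB-ABCFPfA replicate 3 (0.434) and with both left out (2.30e-07), with 8.05e-13 to 0.732 over the libraries left out in turn. The glycerol list (0.155) and the lysine and threonine list (0.868) reversed with both left out. These libraries carried the ribosomal deviations of -0.92 and 0.86. Among the lists that passed, the direction and side of the threshold were kept in 45 list results and lost in 10 for S-AB, kept in 46 and lost in 9 for SfB-ABCFPfA, and between them kept in 58, lost in 25 and reversed in 5. For the named genes, 646 results were kept, 55 missed the threshold and 1 moved in S-AB, 698 were kept and 61 missed it in SfB-ABCFPfA, and 71 were kept and 4 moved between them.

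Of the genes higher in both strains, 132 had a log2 fold change of at least 1 in each, since that limit asks for more. Genes near absent numbered 13 at a limit of 30 counts, which is wider by construction. The deviations of same-numbered libraries from their strain means correlated across genes at -0.38 to 0.48. By these deviations, 3 of 9 libraries correlated best with a library of their own number among the other strains. The replicate number was used as a block only as an alternative. Leaving out rRNA and tRNA was not run, as the table held none. Depth limits low genes: 3 counts were 0.412 to 0.898 CPM.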

Other observations

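The GO term tests and the genes named in this part were chosen after the data were seen; the calls of single genes come from the planned edgeR test. GO process terms with 5 to 300 tested genes were tested with camera, 210 terms in all, and with an estimated correlation none passed.

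Genes of amino acid transport were lower in both strains: of 42, 13 fell and 1 rose in each, with median log2 fold changes of -0.63 in S-AB and -0.64 in SfB-ABCFPfA (adjusted p = 6.06e-05 and 6.22e-05 by camera; adjusted p = 0.529 and 0.412 with an estimated correlation). proX, for the binding protein of a glycine betaine transporter, fell from 224 ± 34.9 CPM in Star to 62.6 ± 4.92 and 52.9 ± 32.8 CPM.

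Of 12 genes for the lipopolysaccharide core, 6 rose and 1 fell in S-AB and 6 rose in SfB-ABCFPfA (medians 1.28 and 1.31; adjusted p = 0.0381 and 0.0235 by camera; adjusted p = 0.536 and 0.429 with an estimated correlation), among them waaJ, at 43.3 ± 9.19, 120 ± 55.7 and 125 ± 39.7 CPM in Star, S-AB and SfB-ABCFPfA. Of 7 genes of restriction and modification, 3 and 4 rose (adjusted p = 0.0354 and 0.00131 by camera; adjusted p = 0.536 and 0.412 with an estimated correlation), and mrr had 44.9 ± 4.02, 89.9 ± 11.3 and 101 ± 4.27 CPM. Of 5 galactitol genes, 3 and 4 fell (adjusted p = 0.0214 and 0.000146 by camera; adjusted p = 0.536 and 0.412 with an estimated correlation). Gene 1_1568 of the GatC family fell from 7404 CPM to 1820 and 1092 CPM.

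speD, for the decarboxylase that makes the aminopropyl donor for spermidine, lies beside speE and rose from 41.8 ± 6.14 CPM in Star to 135 ± 34.9 and 153 ± 59.0 CPM (adjusted p = 0.00624 and 0.00379). frr, for the factor that recycles ribosomes after termination, rose from 225 ± 22.4 to 616 ± 74.5 and 662 ± 160 CPM (adjusted p = 0.00397 and 0.00288).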
